A study of Mus musculus with 6 samples.

How the data were processed

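Whole-transcript expression was measured on 6 Affymetrix gene arrays hybridised with RNA from BV-2 cells, 3 labelled control and 3 labelled LPS. Per the labels' protocols, cells were plated in medium with reduced serum, LPS was added at 1 µg/mL, RNA was isolated with TRIzol and chloroform, and biotin-labelled cDNA was prepared with the GeneChip WT PLUS kit. The labels of the LPS arrays give a time of 24 h, and the time at which control cells were collected was not given in the sources used here. Labels number the replicates of each group from 1 to 3 and do not say whether these came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

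The values were log2 expression values per transcript cluster as deposited in the authors' value table, made with Affymetrix Expression Console per the submitters' processing notes. Neither the version of that program nor its background correction, normalization and summarization method is given in the sources used here. The scale was read from the values, which ran from about 0.84 to 12.0 with array medians between 2.88 and 2.97. As the background correction is not given, fold changes from low signals may be biased, which could not be checked. As a guide to background, the 1446 rows named for olfactory, vomeronasal or taste receptors, genes not known to be used by such cells, had a 95th percentile of 3.13 on the log2 scale. For arrays, the number of arrays limits the precision of each value.

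The table held 41345 rows, called transcript clusters here, each a group of probes for 1 transcription unit. Names came from a probe table of platform annotation, and list members under an older name were looked up through the synonyms of RefSeq genes. Of rows with 1 symbol, 23328 matched a RefSeq gene (GRCm38.p6) by gene identifier, and the symbol was the same in each. The table gave 1 symbol for 23521 rows, several symbols for 1814 and none for 16010. No gene was named from a row with several symbols, except where the text says so. No coordinates are given, since no genome build was named for the array. Of the rows without a symbol, 5333 were numbered before the first named row, and some of these may be array controls, which could not be told from other rows and stayed in the test. A further property of the table is that 1396 rows shared all 6 values with another row.

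The comparison of LPS with control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without a trend) to the deposited values, with no further normalization and no filter. P-values were adjusted by the Benjamini-Hochberg method over all 41345 rows, and rows with adjusted p under 0.05 were called. Fold changes are LPS over control, errors of fold changes are moderated standard errors (SE), and errors of group means are standard deviations (SD) of 3 arrays. A total of 31 gene lists, with 669 entries, was tested with camera, which sets the members of a list against all other genes, at a preset correlation between genes of 0.01. One row per gene was used (the row with the highest mean), which gave 22180 genes, and 597 of the 669 list entries had such a row. Camera p-values were adjusted over the 31 lists. Fry, an alternative, tests whether the genes of a list shift one way, without setting them against other genes. Counts of list members past adjusted p 0.05 are given over all rows and adjusted over the list alone. RNA classes were read from the form of the symbol.

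Groups, tests, gene lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule named the 12 genes with the largest rise and the 12 with the largest fall among called rows of 1 symbol without overlap between groups, up to 4 called members of each list or, where none was called, the 2 members with the highest mean, and 13 genes whatever their values. No row was called lower, so no gene was named for a fall, and 1 of the 13 genes, Mir155, had no row of its own but shared one with Mir155hg.

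The fit was tested on simulated data for LPS against control with the real means and spread of the 41345 rows. Of 50 rows changed at each size, 20% were called at a log2 change of 1, 68% at 2, 92% at 3 and 92% at 4, and 7 of the 143 rows called had not been changed. Changed rows were drawn from all rows, which had a median level of 2.90, and no simulated array deviated as a whole. These shares may therefore not hold for brighter genes that vary between the real arrays. Camera called 5 of 5 shifted sets and 0 of 15 unshifted sets. Simulated rows were independent of each other, so this cannot show how camera behaves where genes of a list vary together. In the real lists the estimated correlation between genes ran from -0.07 for lymphocyte markers to 0.78 for type I interferon-stimulated genes. Alternatives covered quantile normalization, median centring, leaving out dim rows, rows with a name only, 1 row per gene, an intensity trend with robust estimation, an unmoderated fit, the replicate number as a block, leaving out each array, and for lists an estimated correlation, fry and the mean of all rows of a gene. Array weights and settings that treat control replicate 2 and LPS replicate 3 apart were added after the data were seen.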

Results

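BV-2 is a mouse microglial cell line immortalised by a retrovirus that carries raf and myc oncogenes, and microglia are the resident macrophages of the brain. Lipopolysaccharide (LPS) from Escherichia coli O111:B4 is a bacterial cell wall component that is sensed through Toll-like receptor 4. The series compared the transcriptome of BV-2 cells given LPS at 1 µg/mL for 24 h with that of control cells, on 3 arrays per group. Medians of log2 expression were 2.92, 2.89 and 2.91 in control replicates 1 to 3 and between 2.88 and 2.97 in the LPS replicates. Upper quartiles differed more, at 5.00, 4.85 and 4.98 in the controls and 4.92, 5.11 and 5.27 in the LPS replicates. Rows were also binned by their mean in control replicates 1 and 3. Control replicate 2 had median differences from these of -0.39, -0.62 and -0.53 at levels of 5 to 7, 7 to 9 and 9 to 13. The control mean of brighter rows is therefore lower with this array, which bears on the counts of higher and lower rows below. Pearson's r over all rows was 0.982 between control replicates 1 and 3, and control replicate 2 had 0.960 and 0.959 with these. Control replicate 2 had an r of 0.968 with LPS replicate 3, above its r with either other control, but over rows with a symbol the order turned (0.977 against 0.978 with each other control). The first principal component, with 32.3% of the variance, set control replicate 2 apart from the other 5 arrays, and the second, with 26.5%, separated the groups. These r are across rows of 1 pair of arrays, and rows are not independent replicates.

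**Figure D1:**
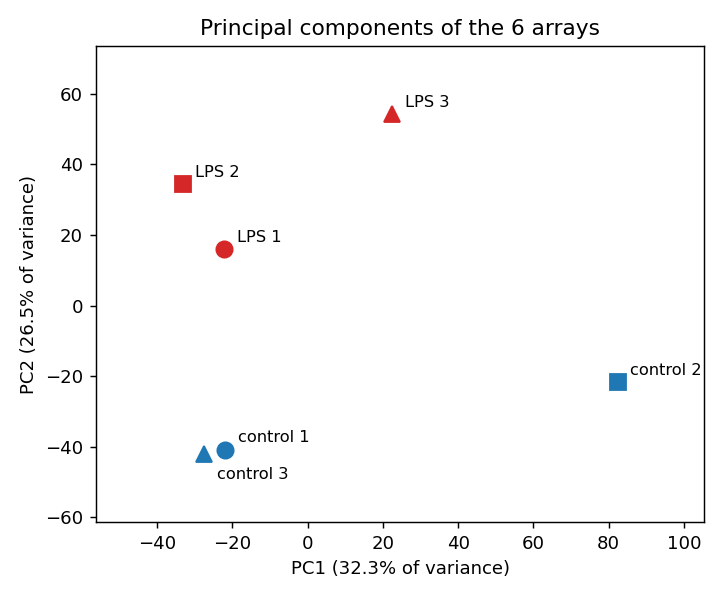
Scores of the 6 arrays on the first (x axis, 32.3% of variance) and second (y axis, 26.5%) principal components of the log2 values, without units, with control arrays in blue, LPS arrays in red and 1 marker per array. Control replicate 2 lies at 82.4 on the first component and LPS replicate 3 at 22.4, while the other 4 arrays lie below 0.

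LPS raised a set of inflammatory genes by large factors. The largest rise was that of Acod1 (transcript cluster 17302475), the enzyme that makes itaconate, from 4.12 ± 0.60 to 10.72 ± 0.08 on the log2 scale (SD, n = 3), a log2 fold change of 6.60 (SE 0.29, limma adjusted p = 0.0012) or 97.1-fold. The interleukin 1 cytokines Il1a and Il1b rose by 6.15 (SE 0.24, adjusted p = 0.00098) and 5.43 (SE 0.39, adjusted p = 0.0073) log2 units. The acute phase genes Saa3 and Lcn2, the latter coding for an iron-siderophore-binding protein, rose by 5.99 (SE 0.47, adjusted p = 0.011) and 5.95 (SE 0.13, adjusted p = 6.0e-05). In all, 80 of 41345 rows were higher after LPS and 0 were lower at adjusted p under 0.05 in limma, and each of the 80 changed at least 2-fold. At an unadjusted p under 0.05, 2059 rows were higher and 578 lower, or 1514 and 1290 after quantile normalization. These numbers were 2057 and 1645 without control replicate 2 and 1992 and 1135 without LPS replicate 3. Without any other array, between 353 and 432 rows were lower. At adjusted p under 0.05, the unmoderated fit called 1 higher and 0 lower.

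The rest of the 12 genes with the largest rise were Ccl5, Rsad2, Cmpk2, Il6, Cxcl2, Ccrl2 and Slamf7, with log2 fold changes between 4.41 for Slamf7 and 5.41 for Ccl5. Control means of Il6 (1.91) and Cxcl2 (2.75) lay within the range of chemosensory receptor rows, so their folds of 32.2 and 31.2 rest on a signal near background. The called rows held 64 with 1 symbol, 6 with several and 10 with none, and 77 distinct profiles. All 80 had LPS values above every control value. Among all rows, 3199 lay wholly above and 1439 wholly below, together 11.2%, where chance gives 10%, shared evenly between the directions. The number wholly below was thus under chance. The number called was 15 without control replicate 1, 22 without control replicate 3, 27 without LPS replicate 1 and 17 without LPS replicate 2. It was 53 higher and 14 lower without control replicate 2, and 76 higher and 6 lower without LPS replicate 3. The 13 of the 80 rows called in each of these 6 fits were those of Acod1, Il1a, Lcn2, Rsad2, Il6, Cxcl2, Ccrl2, Slamf7, Cxcl10 and Nfkbia and, named after their values were seen, Marco, Clec4a1 and Zc3h12c.

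**Figure D2:**
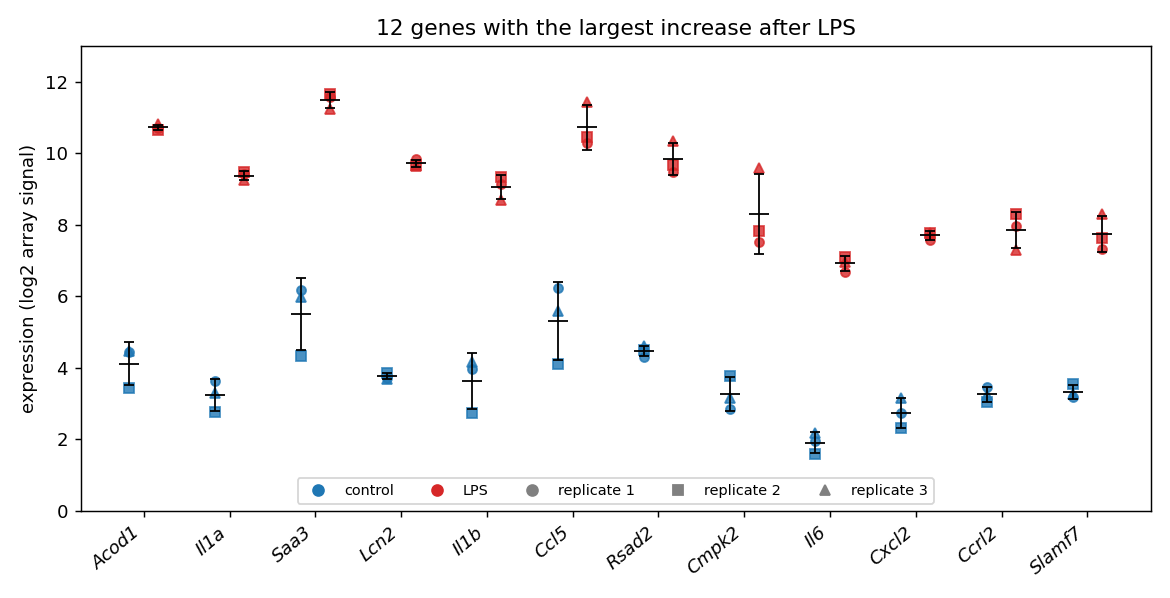
Log2 expression (y axis) of the 12 genes with the largest rise (x axis) on each control (blue) and LPS (red) array, with a marker shape per replicate number. Horizontal ticks are means and bars are SD of 3 arrays, and every LPS value lies above every control value, as for Acod1 at 10.72 ± 0.08 against 4.12 ± 0.60.

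Among 23 inflammatory cytokines, 4 rose, 0 fell and 19 did not pass. Besides Il1a, Il1b and Il6, Tnf rose from an already high 7.88 ± 0.65 to 10.60 ± 0.11 (SD, n = 3), by 2.71 log2 units (SE 0.32, adjusted p = 0.044). Adjusted over the list alone 5 were higher, the fifth being the interleukin 1 receptor antagonist Il1rn (log2 fold change 1.33, adjusted p = 0.14 over all rows), which was singled out after its values were seen. The list was shifted up in camera (adjusted p = 7.5e-05, and adjusted p = 0.32 with an estimated correlation), with a median of 0.12 that was 0.46 without dim rows and -0.00055 with control replicate 2 and LPS replicate 3 both left out, a setting chosen after the data were seen. Of 21 chemokines 4 rose: the T cell and monocyte attractants Ccl5 and Ccl2 (1.68, SE 0.20, adjusted p = 0.044), the neutrophil attractant Cxcl2, and Cxcl10 (4.14, SE 0.24, adjusted p = 0.0034). Adjusted over the list alone, 9 chemokines were higher and 1 was lower, Ccl6, at -1.03, named after its value was seen. Camera gave an adjusted p = 4.5e-09 for the chemokines, and adjusted p = 0.18 with an estimated correlation. Of 14 acute phase genes 3 rose, Saa3, Lcn2 and the protease inhibitor Slpi (3.45, SE 0.34, adjusted p = 0.025), and 5 were higher adjusted over the list alone. The camera adjusted p was 7.0e-05, and adjusted p = 0.18 with an estimated correlation. Called cytokines numbered 2 without control replicate 1, LPS replicate 1 or LPS replicate 2, called chemokines 2 without these or control replicate 3, and called acute phase genes 1 without control replicate 3, LPS replicate 1 or LPS replicate 2, 2 without control replicate 1 or 2, and 5 without LPS replicate 3. Quantile normalization, median centring and an intensity trend with robust estimation each ended the call of Ccl2.

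On the list of nitric oxide and lipid mediator enzymes, which also holds genes outside these pathways, 2 of 16 genes rose. They were Acod1, which makes itaconate, and the NADPH oxidase subunit Cybb (1.30, SE 0.13, adjusted p = 0.029). The inducible nitric oxide synthase Nos2 went from 5.02 ± 0.65 to 8.19 ± 0.66 (SD, n = 3), a log2 fold change of 3.17 (SE 0.43) that did not pass over all rows (adjusted p = 0.079). The prostaglandin synthase Ptgs2 had a log2 fold change of 3.09 (SE 0.75, adjusted p = 0.36), with control replicate 2 at 5.15 and the other controls at 7.78 and 7.94. Adjusted over the list alone 8 members were higher, Nos2 and Ptgs2 among them. The list had a median of 0.85, or 0.54 with control replicate 2 and LPS replicate 3 both left out, and a camera adjusted p = 4.5e-09, and adjusted p = 0.24 with an estimated correlation. With both of these arrays left out Nos2 and Ptgs2 passed and Cybb did not, and with them as a block all 3 passed. The call of Cybb was also lost in each fit with 1 array left out, after quantile normalization and with an intensity trend. The number called was 2 without LPS replicate 3, Acod1 and Nos2, and 1 without any other array, and Nos2 also passed once dim rows were left out and with array weights.

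Of 21 genes of NF-kappaB feedback and survival, 5 rose and 16 did not pass over all rows, while 20 were higher adjusted over the list alone. The inhibitor of NF-kappaB Nfkbia rose by 2.57 (SE 0.17, adjusted p = 0.0054), the signalling inhibitor Irak3 by 2.52 (SE 0.30, adjusted p = 0.044), the ubiquitin-editing enzyme Tnfaip3 by 2.39 (SE 0.28, adjusted p = 0.046) and Bcl3 by 2.18 (SE 0.15, adjusted p = 0.0054). The fifth was Traf1 at 2.13, named after its value was seen. All 21 log2 fold changes were above 0, with a median of 1.72. The camera adjusted p was 1.3e-34, and adjusted p = 0.096 with an estimated correlation. The number called was 4 without LPS replicate 3, 3 without control replicate 2, and 1 or 2 without any other array, and Irak3 missed the threshold after quantile normalization. The number was 8 without dim rows and 10 with named rows only or 1 row per gene, where fewer rows are tested.

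Type I interferon-stimulated genes had a median of 2.00 over 35 members, all with a log2 fold change above 0. It was the highest of the list medians, except without LPS replicate 3 (1.59, against 1.63 for NF-kappaB genes) and without dim rows (2.14, against 3.28 for the 6 acute phase genes left). Of these 7 rose and 28 did not pass over all rows, and 30 were higher adjusted over the list alone. The antiviral enzyme Rsad2 (viperin) rose by 5.36 (SE 0.24, adjusted p = 0.0012), its genomic neighbour Cmpk2 by 5.04 (SE 0.55, adjusted p = 0.037), the oligoadenylate synthetase-like gene Oasl2 by 3.72 (SE 0.44, adjusted p = 0.044) and Rtp4 by 3.47 (SE 0.32, adjusted p = 0.020). The other 3, named after their values were seen, were Oasl1 (3.36) and the cytoplasmic RNA sensors Ifih1 (2.45) and Ddx58 (1.96). Members had a median 1.49 higher in LPS replicate 3 than in the other LPS replicates, at percentile 100 among 10000 random lists of similar level. Genes of such random lists were drawn independently, so genes that vary together reach an extreme percentile more easily, here and below. The list had a camera adjusted p = 6.8e-44, and adjusted p = 0.18 with an estimated correlation. The number called was 13 without LPS replicate 3, 2 without control replicate 2, 2 without LPS replicate 1 and 1 without any other array, and 17 with control replicate 2 and LPS replicate 3 both left out.

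Of 12 interferon-inducible GTPases, Gbp7 (4.39, SE 0.32, adjusted p = 0.0080) and Gbp3 (3.07, SE 0.31, adjusted p = 0.030) rose, and 5 were higher adjusted over the list alone. The control mean of Gbp7, 3.11, and that of Rtp4, 3.00, lay within the range of receptor rows. The camera adjusted p was 2.9e-07, and adjusted p = 0.18 with an estimated correlation. Of 17 MHC class I presentation genes 0 passed over all rows in limma, 6 were higher at an unadjusted p under 0.05, and 5 were higher adjusted over the list alone. The most abundant member, B2m, the light chain of class I molecules, went from 11.67 ± 0.07 to 11.69 ± 0.19 and H2-K1 from 8.41 ± 0.07 to 9.34 ± 0.56 (SD, n = 3; adjusted p = 0.52). The class I list had a median of 0.65 and a camera adjusted p = 2.3e-07, and adjusted p = 0.32 with an estimated correlation. Fry, which tests for a shift of the list itself and not against other genes, gave an adjusted p = 0.22. Relative to the other LPS replicates, LPS replicate 3 was higher by a median of 0.88 for the GTPases and 0.90 for class I genes, and the median log2 fold change of the GTPases, 1.07, was 0.62 without it. The GTPases called numbered 0 without control replicate 1 or LPS replicate 2, 2 without LPS replicate 3 and 1 without any other array.

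Of 26 pattern recognition and inflammasome genes 3 rose and 23 did not pass. These were Clec4e, a receptor for mycobacterial glycolipid (2.56, SE 0.17, adjusted p = 0.0054), the LPS co-receptor Cd14 (1.41, SE 0.17, adjusted p = 0.046) and Tlr2, a receptor for bacterial lipoproteins (1.36, SE 0.16, adjusted p = 0.042). The LPS receptor Tlr4 went from 6.19 ± 0.51 to 6.16 ± 0.09 (SD, n = 3), a log2 fold change of -0.04 (SE 0.26, adjusted p = 1.00). Adjusted over the list alone 9 were higher and 1 was lower, Tlr8 at -0.62, named after its value was seen. The camera adjusted p was 0.00011, and adjusted p = 0.39 with an estimated correlation. The list median of 0.43 became 0.13 without control replicate 2 and -0.04 with control replicate 2 and LPS replicate 3 both left out. Of 12 MHC class II presentation genes the costimulatory molecule Cd80 rose (1.66, SE 0.18, adjusted p = 0.038) and 11 did not pass, with the same count adjusted over the list alone. The class II list had a median of -0.07, a mean of 0.09 and a camera test pointing down (adjusted p = 0.89), and its median was -0.18 without control replicate 2, 0.01 without control replicate 1, 0.05 without control replicate 3 and 0.03 without dim rows. Quantile normalization and an intensity trend each ended the calls of Cd14, Tlr2 and Cd80, and median centring those of Cd14 and Tlr2. With the trend 1 pattern recognition gene was called, and with named rows only or 1 row per gene 6. Pattern recognition genes called numbered 0 without control replicate 1, 2 without control replicate 2 and 1 without any other array, and of these fits only the one without control replicate 2 called Cd80.

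Of 19 antioxidant and NRF2 target genes 4 rose, 15 did not pass, and 7 were higher adjusted over the list alone. The cystine transporter Slc7a11 rose by 3.68 (SE 0.29, adjusted p = 0.0099) on its brighter row, and its second row had 1.84 (adjusted p = 0.35). Of the glutathione and thioredoxin genes, Gclm rose by 2.37 (SE 0.28, adjusted p = 0.046), Txnrd1 by 1.86 (SE 0.15, adjusted p = 0.012) and Gsr by 1.39 (SE 0.17, adjusted p = 0.046). The list had a median of 0.83 and a camera adjusted p = 3.4e-10, and adjusted p = 0.18 with an estimated correlation. The median was 0.51 without control replicate 2, 0.53 without LPS replicate 3 and 0.37 without both, and LPS replicate 3 lay 0.32 above the other LPS replicates, at percentile 98.6 among random lists. Its called members numbered 3 without LPS replicate 3, 2 without control replicate 2 and 0 without any other array. Quantile normalization ended the calls of Gclm, Txnrd1 and Gsr, and median centring and an intensity trend that of Gsr.

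No member passed over all rows among 25 genes of endoplasmic reticulum and amino acid stress or 23 lysosome genes, and adjusted over the list alone 0 and 1 were higher, the latter being Sqstm1 (1.51), named after its value was seen. At an unadjusted p under 0.05, each list had 2 higher and 0 lower members. The chaperone Hsp90b1 and the disulfide isomerase Pdia6 had log2 fold changes of 0.03 and 0.12, and the lysosomal genes Ctsa and Cd68 -0.02 and -0.14. Both lists were shifted up in camera (adjusted p = 0.036 and 0.021), and neither with an estimated correlation (adjusted p = 0.61 and 0.73). The lysosome genes had a median of 0.14, or 0.26 without LPS replicate 1 and -0.01 without LPS replicate 3, in which they lay 0.53 above the other LPS replicates. Without LPS replicate 3 the camera adjusted p was 0.53 for the stress list and 1.00 for the lysosome list, and it was 0.20 for the stress list without control replicate 2 and 0.098 for the lysosome list without control replicate 3.

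Of 23 homeostatic microglia genes 0 passed in limma, also when adjusted over the list alone, and at an unadjusted p under 0.05 1 was higher and 5 were lower. The purinergic receptor P2ry12 went from 4.04 ± 0.50 to 3.27 ± 0.19 (SD, n = 3; log2 fold change -0.77, adjusted p = 0.65), the growth factor receptor Csf1r had 0.05 and Mef2a 0.16. The list had a median of -0.11 and was shifted down in camera (adjusted p = 0.0076, and adjusted p = 0.56 with an estimated correlation), a call that ended without LPS replicate 1 (adjusted p = 0.069). Its median was -0.02 without control replicate 1 or control replicate 3, and -0.28 with control replicate 2 and LPS replicate 3 both left out, where Gpr84 was called higher and Ltc4s lower, both named after their values were seen. Gpr84 was also called higher with these 2 arrays as a block. Of 18 alternative activation genes 0 passed, also adjusted over the list alone, and 0 were higher and 4 lower at an unadjusted p under 0.05. The mannose receptor Mrc1 went from 8.83 ± 0.41 to 7.83 ± 0.42 (SD, n = 3; adjusted p = 0.49) and the log2 fold change of Cd36 was 0.29, and the list was shifted down with a median of -0.12 (camera adjusted p = 0.013, and adjusted p = 0.32 with an estimated correlation). With dim rows left out the median of the 11 members left was 0.17 and the call was lost. The median was -0.05 without control replicate 3. Without control replicate 2 it was -0.20 and 1 member, Arg1, named after its value was seen, was called lower, as it was with control replicate 2 and LPS replicate 3 both left out. Disease-associated microglia genes (21 measured, camera adjusted p = 0.28), complement genes (16, adjusted p = 0.29) and matrix protease and adhesion genes (23, adjusted p = 0.86) held 0 called members, and 1, 1 and 2 were higher adjusted over the list alone. At an unadjusted p under 0.05 these lists had 2, 1 and 4 higher and 2, 2 and 1 lower members. The 4 past the threshold over the list alone were Cd52 (1.26), Cfb (3.63), Mmp9 (1.92) and Itga5 (1.74), named after their values were seen. Cfb and Mmp9 were called with named rows only, with 1 row per gene, with array weights and with control replicate 2 and LPS replicate 3 both left out, Cfb also without dim rows or without LPS replicate 3, and Mmp9 also with these 2 arrays as a block. C1qc, also named after its value was seen, was called lower without control replicate 2, and C1qc and Plau with both of these arrays left out. Disease-associated genes passed in camera, pointing down, without LPS replicate 3 (median -0.18, against -0.03 with all arrays and 0.03 without LPS replicate 1), but not with an estimated correlation over all arrays (adjusted p = 0.84). Abundant members had log2 fold changes of 0.14 (Ctsb), -0.03 (Gpnmb), 0.14 (C3ar1), -0.28 (Itgam), -1.11 (Plau) and 0.52 (Sdc4). The complement list had a median of -0.03, between -0.11 and 0.01 over the settings, and a mean of 0.07, with camera pointing down.

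**Figure D3:**
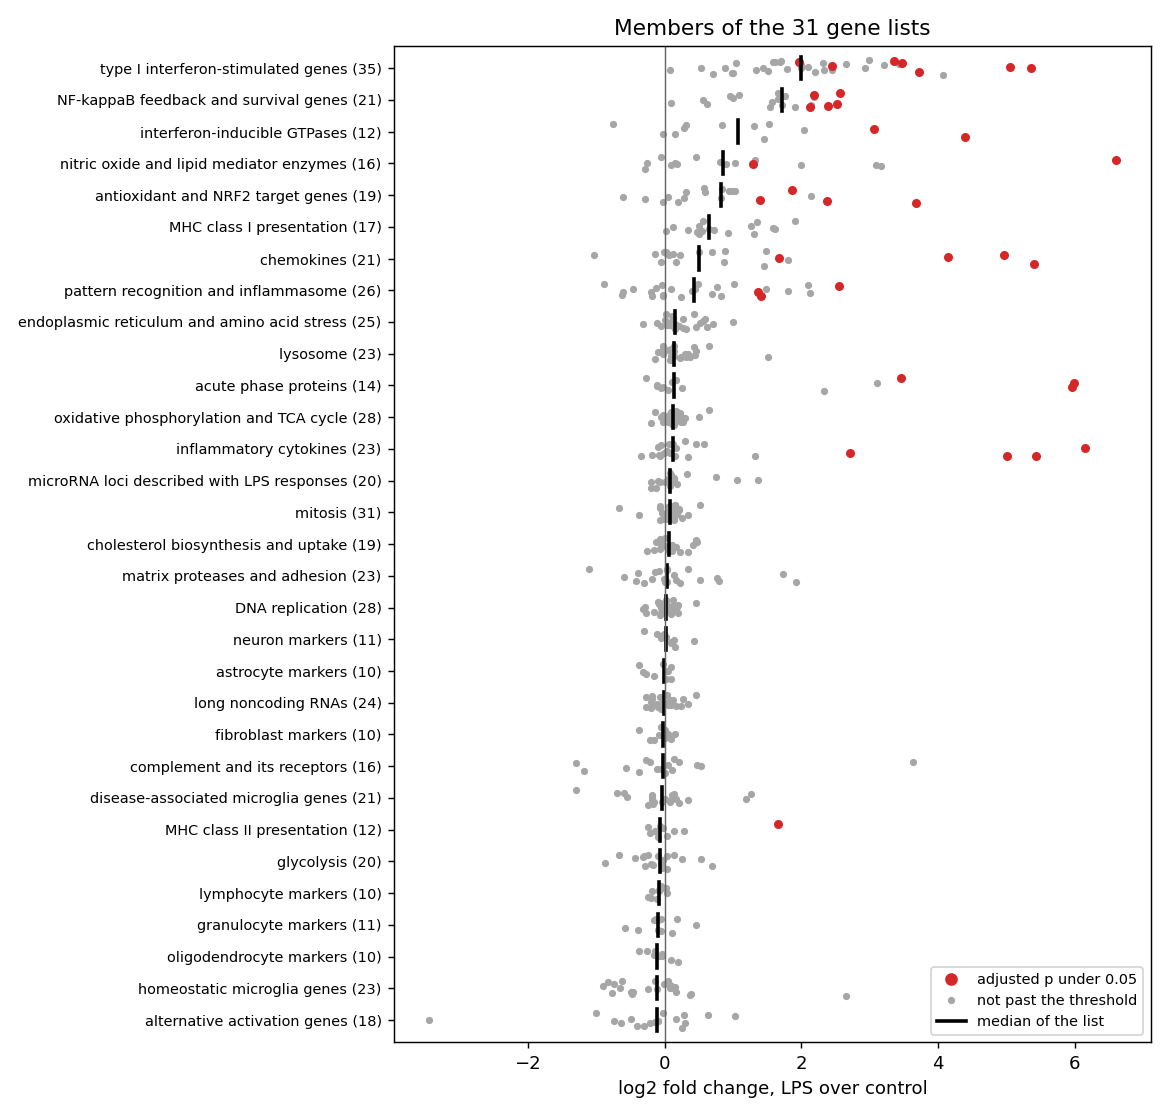
Log2 fold change of LPS over control (x axis) for each measured member of the 31 gene lists (y axis, number of measured members in parentheses), with called members in red, other members in grey and the list median as a black bar. Medians run from -0.12 for alternative activation genes to 2.00 for type I interferon-stimulated genes, and all red points lie above 0.

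Proliferation and metabolism lists held no called gene, over all rows or adjusted over the list alone, and none passed in camera with the settings fixed as primary, while 4 of the 5 did in other settings. At an unadjusted p under 0.05 each of the 5 lists had 1 higher and 0 lower members. Median log2 fold changes were 0.02 for 28 DNA replication genes (adjusted p = 0.45), with camera pointing down, and 0.08 for 31 mitosis genes (adjusted p = 0.73). They were 0.07 for 19 cholesterol genes (adjusted p = 0.58), -0.07 for 20 glycolysis genes (adjusted p = 0.16) and 0.12 for 28 genes of oxidative phosphorylation and the TCA cycle (adjusted p = 0.29). Scaling and single arrays moved these medians. After quantile normalization they were -0.18, -0.12, -0.13, -0.23 and -0.04 in the same order, and DNA replication and glycolysis genes passed in camera, pointing down. Glycolysis genes also passed, pointing down, with dim rows left out, without LPS replicate 2 and without control replicate 2, where their median was -0.31. Genes of oxidative phosphorylation passed in opposite directions without control replicate 1 (median 0.29) and without control replicate 2 (-0.18). Mitosis genes did so without LPS replicate 3 (0.25) and without LPS replicate 2 (-0.09), and DNA replication genes passed pointing down without LPS replicate 2 (-0.10). The median of the cholesterol genes was -0.12 without LPS replicate 3 and 0.19 without LPS replicate 1, and that of the glycolysis genes -0.02 without control replicate 3. All these camera calls used the preset correlation, and with an estimated correlation, run on the values of all 6 arrays, the adjusted p was 0.90 for DNA replication, cholesterol and oxidative phosphorylation, 0.94 for mitosis and 0.81 for glycolysis genes. The abundant members Pcna, Rrm1, Mki67, Tpx2, Insig1, Nsdhl, Gapdh, Pgk1, Atp5b and Mdh2 had log2 fold changes between -0.09 for Gapdh and 0.34 for Insig1. Glycolysis genes in control replicate 2 had a median difference of -0.94 from the other controls, at percentile 0.020 among 10000 random lists of similar level, and oxidative phosphorylation genes one of -0.92, at percentile 0.010. Mitosis genes in LPS replicate 3 had a median difference of -0.48 from the other LPS replicates, at percentile 0, and in control replicate 2 one of 0.03 from the other controls, at percentile 100.

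Markers of astrocytes (10 measured, camera adjusted p = 0.25), neurons (11, adjusted p = 0.94), oligodendrocytes (10, adjusted p = 0.084), fibroblasts (10, adjusted p = 0.25), lymphocytes (10, adjusted p = 0.061) and granulocytes (11, adjusted p = 0.084) held no called gene, also adjusted over each list alone, and at an unadjusted p under 0.05 fibroblast and granulocyte markers had 1 lower member each. In camera, pointing down, oligodendrocyte, lymphocyte and granulocyte markers passed without LPS replicate 1, lymphocyte markers also without control replicate 3 and granulocyte markers without control replicate 1. With an estimated correlation over all arrays the adjusted p of these lists was 0.32, 0.32 and 0.41. Their most abundant members were mostly dim, such as Rbfox3 at 3.42 ± 0.08, Pdgfrb at 3.49 ± 0.23 and Nkg7 at 4.15 ± 0.04 in control cells (SD, n = 3). The exceptions were Aldoc at 8.43 ± 0.72, which is also a glycolysis gene, and Csf3r at 5.59 ± 0.61.

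The series was also submitted as noncoding RNA profiling. Of 511 rows of microRNA genes, 81 of small nucleolar RNAs, 30 of histone genes and 124 of ribosomal protein genes, 0 were called in limma, and at an unadjusted p under 0.05 these classes had 8, 5, 0 and 0 higher and 10, 0, 0 and 1 lower rows. These classes hold rows with 1 symbol, and 2 of the 6 called rows with several symbols, both higher, include a microRNA symbol. They were the row of Mir155 and Mir155hg (log2 fold change 3.17, SE 0.34, limma adjusted p = 0.034) and that of AA467197 and Mir147 (2.57, SE 0.21, adjusted p = 0.011). The former was called in 1 and the latter, named after its value was seen, in 4 of the 6 fits with 1 array left out. With named rows only or 1 row per gene, 1 microRNA row of 1 symbol was called. The unmoderated fit called 0 in these classes and in the lists without a called member, but it called 1 row in all. Of 2892 rows with predicted or cDNA-derived names 1 was called, higher, and of 1446 chemosensory receptor rows 0. Among 20 microRNA loci described with LPS responses 0 passed over all rows, and adjusted over the list alone Mir221 (1.37) and Mir222 (1.05), named after their values were seen, were higher (camera adjusted p = 0.26), with 3 higher and 0 lower at an unadjusted p under 0.05. Mir221 passed with named rows only and with 1 row per gene. The list entries Mir155, Mir155hg and Mir147 had no row of their own, so they were not among the 20. Whole-transcript arrays read the precursor or host transcript at such loci and not the mature microRNA. Of 24 long noncoding RNAs 0 passed, also adjusted over the list alone or at an unadjusted p under 0.05 (camera adjusted p = 0.29), and the list passed in camera, pointing down, after quantile normalization (median -0.12, against -0.01, and 0.06 without LPS replicate 1), but not with an estimated correlation on the deposited values (adjusted p = 0.77). The abundant Malat1 and Xist had log2 fold changes of 0.17 and 0.08, and a second row of Malat1 had -0.79 (adjusted p = 0.85).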

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

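Settings that leave out control replicate 2 and LPS replicate 3 together or treat them as a block, and array weights, were chosen after the data were seen. Of the 80 rows called, all higher, the count stayed within 1.5 times after quantile normalization, median centring, an intensity trend with robust estimation, leaving out dim rows and 1 row per gene, all without lower calls. It was 130 with named rows only, where fewer rows are tested, 1 in the unmoderated fit, 132 with array weights and 134 with the block of control replicate 2 and LPS replicate 3, in each case with 0 lower. The transcript clusters changed at least 2-fold numbered 126 with named rows only, 131 with array weights and equalled the full count in the other settings of this paragraph. With both of these arrays left out it was 219, 152 higher and 67 lower, on 2 arrays per group. With 1 array left out it ran from 15 to 82 in all, 15 to 76 higher and 0 to 14 lower, with fewer arrays in each fit. With the replicate number as a block it was 7, all higher, and all 14 lists stayed past the threshold. Deviations of same-numbered arrays correlated at 0.07, -0.26 and -0.22, so the numbers gave no sign of pairing. All 33 called genes among the 79 named kept their direction in every setting in which they were tested. Quantile normalization ended 9 of these calls, the intensity trend 6 and median centring 4. The unmoderated fit ended 32 of them, the replicate number as a block 26, and leaving out 1 array between 8 (LPS replicate 3) and 22 (LPS replicate 2). Of the 14 lists past the threshold in camera, 0 stayed with an estimated correlation. In fry, which tests for a shift of the list itself and not against other genes, 8 of them passed. With an estimated correlation the adjusted p was 0.096 for NF-kappaB genes, 0.18 for chemokines, acute phase, interferon-stimulated, GTPase and antioxidant genes, 0.24 for mediator enzymes, 0.32 for cytokines, class I and alternative activation genes, 0.39 for pattern recognition, 0.56 for homeostatic, 0.61 for stress and 0.73 for lysosome genes. In fry it was 0.22 for class I, 0.097 for pattern recognition, 0.66 for homeostatic, 0.46 for alternative activation, 0.50 for stress and 0.57 for lysosome genes. Without dim rows it was 0.18 for alternative activation, 0.26 for stress and 0.25 for lysosome genes, after quantile normalization 0.14 for stress and 0.093 for lysosome genes, and with both arrays left out 0.77 and 0.58 for these. With 1 array left out it ran from 0.00026 to 0.069 for homeostatic, 0.0095 to 0.53 for stress and 0.00012 to 1.00 for lysosome genes. Of lists that did not pass, quantile normalization gave adjusted p-values of 0.0025 for DNA replication, 0.012 for glycolysis and 0.016 for long noncoding RNAs, and leaving out dim rows 0.032 for glycolysis. With both arrays left out these were 0.00086 for glycolysis, 0.018 for disease-associated and 0.00013 for mitosis genes, and with the block of both 0.026 for glycolysis. With 1 array left out they ran from 0.0015 to 0.94 for disease-associated genes, 0.012 to 0.99 for DNA replication, 0.00042 to 0.99 for mitosis, 0.00020 to 0.59 for glycolysis, 0.0039 to 0.93 for oxidative phosphorylation, 0.046 to 0.28 for oligodendrocyte, 0.025 to 0.29 for lymphocyte and 0.0095 to 0.29 for granulocyte markers. The direction turned for mitosis without LPS replicate 2 (0.037) and for oxidative phosphorylation without control replicate 2 (0.039). The cause was not tested for any of these unless stated. A pseudocount was not run, since values were on a log scale. Signals under about 3.13 lie in the range of receptor rows and limit what the fold changes of dim genes can show.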

Other observations

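Genes in this and the next paragraph were chosen after their values were seen. Outside the fixed lists, the scavenger receptor Marco rose from 3.25 ± 0.11 to 7.46 ± 0.34 (SD, n = 3), a log2 fold change of 4.21 (SE 0.20, limma adjusted p = 0.0012). The lectin receptor Clec4a1 rose by 3.59 (SE 0.18, adjusted p = 0.0014), the endoribonuclease gene Zc3h12c by 2.29 (SE 0.14, adjusted p = 0.0039) and the pantetheinase Vnn3 by 2.61 (SE 0.18, adjusted p = 0.0067). The rows of Marco, Clec4a1 and Zc3h12c stayed past the threshold in all 6 fits with 1 array left out, and that of Vnn3 in 4. The death receptor Fas (2.40, adjusted p = 0.012), the enzyme Aoah, which removes acyl chains from LPS (2.43, adjusted p = 0.018), the transcription factor Spic (1.76, adjusted p = 0.018) and the kinase Ikbke (2.17, adjusted p = 0.030) were also higher, Fas and Aoah in 3 of these 6 fits and Spic and Ikbke in 1. Control means of Fas (2.91) and Spic (2.25) lay within the range of receptor rows, so their changes rest on a signal near background.

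LPS replicate 3 stood apart from LPS replicates 1 and 2 in both directions. Ifit1 had log2 expression of 5.44, 6.06 and 8.45 in LPS replicates 1 to 3 and Ifi205 5.27, 5.25 and 9.57. The acute phase genes Hp (7.89, 8.34 and 5.35) and Cp (7.19, 7.32 and 4.75) and the chemokine Ccl7 (7.23, 7.55 and 4.71) were lower on that array. The LPS co-receptor component Ly96 had 6.31, 6.64 and 9.40, the matrix protease Mmp12 4.41, 4.11 and 7.90, and Itgax 4.12, 5.10 and 7.07. On the control side, arginase Arg1 had 10.23, 4.82 and 10.32 in control replicates 1 to 3 and 4.90, 5.47 and 4.66 in the LPS replicates.

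Tests of whether control replicate 2 was treated or mixed, of glycolysis genes, of the spread from single arrays and of the direction in the remaining pair of arrays were chosen after the results they address were seen. The real grouping called 80 rows, the other 9 of the 10 splits of the 6 arrays into 3 and 3 called 0, and 1 split reached 80, the real one. With 10 splits the share cannot fall under 0.05, so this cannot tell the calls from chance. Each other split mixes control and LPS arrays in both groups, so a true difference would raise the spread there and lower the calls.

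Control replicate 2 and LPS replicate 3 deviated from their groups together, with a correlation of deviations of 0.27 over all rows. Control replicate 3 and LPS replicate 2 did so as well (0.25) and more over rows with a symbol (0.31, against 0.24). Deviations of the arrays of a group sum to 0, so these correlations are not independent of each other. A scaling that depends on signal level alone would lower the correlation of control replicate 2 with LPS replicate 3 when removed. That correlation was 0.32 once a loess trend with level was removed from each array. Risen list genes argue against treatment of control replicate 2 like the LPS arrays. The 41 with a median rise of 3.09 in the other arrays had a median difference of -0.31 from the other controls there (bootstrap 95% interval -0.63 to 0.020), and 15 lay above them. The bootstrap treats genes of 1 array that vary together as independent, and the level trend was not removed. The interval thus does not measure the uncertainty of the array, and a small share of treated cells cannot be told apart from none. Genes that fell were not used. Arg1 lay at 4.82 in control replicate 2, near its LPS mean of 5.01, but Hspb7, at 9.15, near the other controls (9.21 and 9.67), both picked after their values were seen. A shared difference in culture stays open as an explanation. Glycolysis genes lay at or below percentile 0.34 of matched random lists in both arrays (medians -0.94 and -0.27), and oxidative phosphorylation genes did so too (medians -0.92 and -0.23). Other lists lay at high percentiles in both arrays. These were type I interferon-stimulated genes (medians 0.0013 and 1.49, percentiles 99.97 and 100), lysosome genes (-0.10 and 0.53, 99.75 and 99.98) and disease-associated genes (-0.17 and 0.44, 98.09 and 99.86). Mitosis genes lay at opposite ends (medians 0.03 and -0.48, percentiles 100 and 0), and no label names a batch. Genes of the random lists were drawn independently, while the estimated correlation was 0.50 within the glycolysis list and 0.77 within that of oxidative phosphorylation. An extreme percentile is therefore no support for this explanation by itself.

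The 1439 rows that lay wholly below were fewer than an even share of the 10% that chance gives for both directions, and no row was called lower. Rows near the floor that cannot fall do not account for the lack of lower calls among brighter rows. Among 6722 rows with a control mean of at least 6, 15 were called higher and 0 lower, and 563 were higher and 87 lower at an unadjusted p under 0.05 in limma. Rows wholly below were not counted there, so a floor effect on their number stays open. Control replicate 2 lay below the other controls at such levels, which may add to this imbalance. Whether spread from the 2 arrays contributes stays open. Without control replicate 2, 14 rows were called lower, with 6 without LPS replicate 3 and 0 without any other array. Among the 14 were Arg1 at -5.27, Ndrg1 at -2.34 on its brighter row and -3.13 on the other, and C1qc at -1.59, named after their values were seen. With both arrays as a block and with array weights 0 were called lower, and 134 and 132 higher. The block gives both arrays a shared offset, so it cannot take up deviations of opposite sign, and its 0 does not count against such spread. At an unadjusted p under 0.05 in limma, 578 rows were lower with all arrays, 1328 with array weights and 789 with the block. With both arrays left out, on 2 arrays per group, 2370 were lower. Of the 67 rows called lower in the other 4 arrays, 31 (46.3%, Wilson 95% interval 34.9 to 58.1) were lower in LPS replicate 3 than in control replicate 2, against 34.2% of all rows, and 52 (77.6%, 66.3 to 85.9) once the level trend of that difference was removed, against 50.5% of all rows. Of 152 rows called higher, 145 (95.4%) and 141 (92.8%) were higher there, but 1 array per group gives a row no spread, so these shares exclude nothing and a fall after LPS stays open as a biological explanation.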
